A study of Homo sapiens with 8 samples.

How the data were processed

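Total RNA of 4 established non-small cell lung cancer lines, with 1 DMSO array and 1 SW151511 array per line, was labelled with biotin and hybridised to Illumina bead arrays, per the labels' protocols. Per the file headers, the deposited raw values are the mean bead intensity of each of 47323 probes on each array on a linear scale, not normalized between arrays, with the standard error of the bead intensity and the number of beads. The deposited p-value of each probe on each array, per the file headers, is its detection p-value against background. A further set holds the authors' processed values, which behave as log2 intensities with near-equal array medians of 6.78 to 6.79, and which rank the probes of an array exactly as the raw intensities do (rank correlation 1). Which transform and normalization the authors used for these log2 values is not given in the sources used here. The tool lumi is named in the submitters' processing notes, without a version or a role. Scanner software and the slide of each array are not given in the sources used here, so batches were not tested. No per-sample column was left unused.

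Sample groups came from the phenotype and treatment labels, with H596 and H2122 as sensitive and HCC366 and H661 as resistant. DMSO and treated arrays of a line were paired by the cell line label, and the pairing was checked on the values: deviations of the paired arrays from the mean of their treatment correlated across genes by 0.804 to 0.959. Median raw intensity per array was 109.4 to 115.7, the percent of probes with a detection p under 0.05 was 41.8 to 45.0, the median number of beads was 20 and the median bead error was 3.33% to 3.68% of the intensity. For arrays, their number limits the precision.

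Raw intensities were background corrected, quantile normalized and log2 transformed with neqc of limma 3.58.1 in R 4.3.3 (with version 1.17.8 of data.table), with control values inferred from the detection p and an offset of 16. Probes with a detection p under 0.05 on at least 2 of the 8 arrays were kept, 25564 in number. Probes were named from the reference tables of genes, in which 30113 probes matched a single gene, 8 several and 17202 none, and 19086 of the kept probes named 13907 genes. A gene with several kept probes (3952 genes) was represented by the probe with the highest mean over all arrays. Of the 830 genes on the fixed lists, 55 had no match there. Figures were drawn with python 3.11.15, matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3.

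Comparisons, alternatives, 45 gene lists and the rule for named genes were fixed before the data were examined, except where the text says otherwise. The 5 comparisons were tested with limma (lmFit and eBayes), two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The effect over all 4 lines used line as a block (3 residual degrees of freedom). Effects in the sensitive and resistant lines and their difference came from 1 model with a coefficient per line and a treatment coefficient per phenotype (2 residual degrees of freedom), and the difference under DMSO from the 4 DMSO arrays. An exact test of 2 lines against 2 cannot give a two-sided p under 0.333, so none is reported. Where a gene was not detected on any array of a side, its fold is a lower bound computed against the lowest normalized signal of a detected probe on each array (log2 4.74 to 4.85). The change of a line is bounded likewise where its gene was detected on 1 of its 2 arrays. A gene detected on some arrays of a side keeps its fitted value, in which the other arrays enter at background. Medians of lists with bounds leave out genes detected on neither side, and genes whose detected side does not exceed that lowest signal. Gene lists were tested with camera of limma at a preset correlation of 0.01, adjusted over the 45 lists, and with an estimated correlation and with fry as alternatives. In each line a list's median was also ranked among 10000 random lists of the same size, matched on mean expression in 20 bins. List medians of the difference between phenotypes are not given with bounds, since a bound on each effect gives none on their difference.

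Named per comparison are up to 12 called genes in each direction with the largest change and the same sign in every line. Where fewer than 8 qualified, genes were filled up to 8 by the smallest unadjusted p among those changed at least 2-fold and then among the rest, and are given as not past the threshold. Up to 4 members of a passing list with the smallest unadjusted p, and per line the 5 largest rises and falls among genes detected on both arrays, were added. A part of these genes is printed. Probes annotated to microRNA genes and uncharacterised loci are not reported, because the arrays do not tell which transcript form such a probe measured. Probes with no gene or several were tested apart, without names.

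The limma fit was tested on simulated data made from the values of these 13907 genes, with 200 genes changed in each of 20 draws. At a log2 change of 1 it called 95.4% of the changed genes over all 4 lines, 67.1% in the sensitive lines, 66.5% in the resistant lines, 15.8% for the difference and 0% under DMSO. At a log2 change of 2 it called 99.7% of the changed genes over all 4 lines, 99.7% in the sensitive lines, 99.4% in the resistant lines, 96.2% for the difference and 2% under DMSO; at 4 it called 76.4% under DMSO and 100% in the others. Between 6.25 and 16.8 unchanged genes were called per draw, 6.75% to 8.37% of the calls, more than the 5% aimed at. The simulated changes were equal in every line, genes varied independently of each other, and noise was drawn at the already moderated variance of each gene. These shares are therefore no measure of power in the real lines. In the real sensitive lines, genes with a mean log2 change above 2, such as LIPG, were not called. For the sensitive lines, a list of 10 genes moved by a log2 change of 1 was called by camera in 20 of 20 draws, and 1 list was called over 20 draws of 45 lists with no change. Genes varied independently in these draws too. The counts are therefore no error rate of the list test for real lists, whose members can vary together.

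Alternatives were an offset of 50, no background correction, the authors' values, no detection filter, detection on all 8 arrays, the mean of a gene's probes, every probe on its own, eBayes with trend and robust settings, a fold of at least 1.5, each line left out, no line block, the 4 arrays of a phenotype alone, the mean of both phenotypes' effects, and all 8 arrays with line as a random block for the difference under DMSO. Arrays scaled to equal medians, for the size of the response and for the list counts, the list counts without background correction and with an offset of 50, and the count of changed genes among those detected on both arrays of a line were added after seeing the data.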

Results

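Gene expression was measured in 4 established human non-small cell lung cancer lines, each kept for 24 h with the compound SW151511 at 10 µM or with its vehicle, DMSO at 0.1%. H596 and H2122 carried the label sensitive to SW151511, and HCC366 and H661 the label resistant. Each line gave 1 array per treatment, so the 4 groups of phenotype and treatment held 2 arrays each, and the members of a group were different cell lines. No line had a repeat culture, so values of a line carry no error. Errors given as ± are limma's moderated standard errors of the fitted mean over lines (n = 2 lines per phenotype, n = 4 over all lines). Their variance is drawn toward that of all genes and, where phenotypes are fitted, pooled over both. They therefore do not show how far the 2 lines of a phenotype differ, which can be more. The median raw intensity of the arrays lay between 109.4 and 115.7, and between 41.8% and 45.0% of the 47323 probes were detected above background. A probe's intensity was the mean over a median of 20 beads. The number of arrays limits the precision. After filtering, 13907 genes were compared.

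The size of the response in each line was compared first. H596 had 429 genes at least 2-fold higher and 577 at least 2-fold lower after treatment, and H2122 had 273 and 131. In HCC366 58 genes were at least 2-fold higher and 11 lower, and in H661 2 were higher and 8 lower. The standard deviation of the log2 changes over genes was 0.57 in H596, 0.43 in H2122, 0.30 in HCC366 and 0.22 in H661. On the 12917 brightest probes the spread of the changes was 3.55, 2.75, 1.91 and 1.27 times that given by the scatter between beads, which covers the measurement within an array and not differences between cultures or hybridisations, so a ratio above 1 is no test of the compound. Among genes detected on both arrays of a line, the largest rises in H596 were those of CYP1A1 (64.1-fold), a cytochrome P450 of foreign compounds, the collagenase gene MMP1 (23.6-fold), the AP-1 subunit gene FOSL1 (log2 change 4.32), the interleukin-33 receptor gene IL1RL1 (16.7-fold) and the inducible chaperone gene HSPA6 (15.0-fold). TNFSF10, which encodes the death ligand TRAIL, was 13.2-fold lower there, the transcription factor gene SOX2 9.26-fold, PPFIBP2 12.3-fold and LYPD1 10.4-fold. In H2122 CYP1A1 was 150-fold higher, the adhesion receptor gene ADGRF1 14.7-fold, the retinaldehyde dehydrogenase gene ALDH1A3 10.3-fold and the epidermal gene S100A7 9.73-fold. SMOC1, DMBT1, NR4A2, SIK1 and SLC7A2 were between 3.35-fold and 4.48-fold lower in H2122. In HCC366 the hormone gene STC2 was 5.76-fold higher, the ADP-ribosyltransferase gene TIPARP 3.23-fold, GCNT3 3.20-fold and VIPR1 3.14-fold, and SNX31, NEIL3, SKA1 and NUDT1 were between 2.04-fold and 2.22-fold lower. In H661 the largest rise among genes detected on both arrays was 1.94-fold (PPP1R3F), and the largest fall 2.70-fold (ZNF713). These per-line values were not tested, since each rests on 1 pair of arrays.

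**Figure D1:**
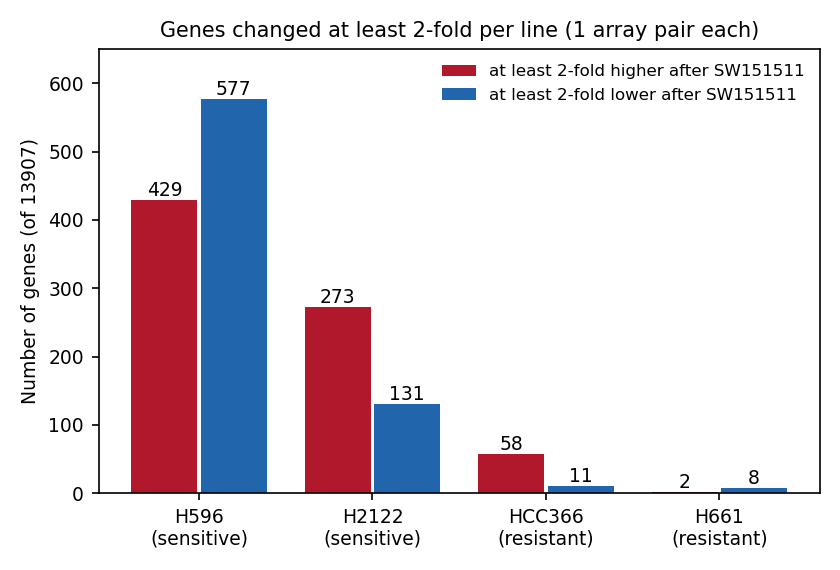
Number of genes (of 13907, y axis) at least 2-fold higher or lower after SW151511 in each line, 1 pair of arrays per line. H596 had 429 higher and 577 lower, H2122 273 and 131, HCC366 58 and 11, and H661 2 and 8.

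Across genes, the changes of H596 and H2122 had a Pearson correlation of 0.0862 and a Spearman correlation of 0.0321, and those of H2122 and HCC366 a Pearson correlation of 0.204, over 6 pairs of lines compared. Genes are not independent replicates, so no p is given. At least 2-fold higher in both sensitive lines were 52 genes, against 8.42 if the lines were independent, and 11 were lower in both, against 5.44. HCC366 shared 15 such rises with H596, against 1.79, and 13 with H2122, against 1.14, so the excess was not particular to the sensitive pair. H661 had too few changed genes for this count. The share of genes changed at least 2-fold was 7.23% in H596, 2.90% in H2122, 0.496% in HCC366 and 0.0719% in H661, and depends on the scaling: with the authors' values it was 2.73%, 0.856%, 0.137% and 0.00719%, in the same order of lines. HCC366 then had 19 genes higher and 0 lower and H661 1 and 0, and with an offset of 50 or without background correction HCC366 also had 0 lower and H661 1 higher and 0 lower. With arrays scaled to equal medians, chosen after seeing the data, the median of all genes moved by 0.10 in H2122 and -0.09 in H596, and the share of the 2-fold changes that were rises went from 42.6% to 28.1% in H596 and from 67.6% to 87.8% in H2122.

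The effect in the sensitive lines asks what SW151511 does to the cells it is said to act on. CYP1A1, the enzyme gene best known as a target of the aryl hydrocarbon receptor, rose in both sensitive lines, with log2 changes of 6.00 in H596 and 7.23 in H2122. In HCC366 it was detected after treatment alone (log2 change at least 0.35), and in H661 on neither array. Its mean log2 change in the sensitive lines was 6.62 ± 0.36 (limma, adjusted p = 0.0163), and it was the 1 gene called of 13907. Next in order, and not past the threshold, were rises of LIPG, an endothelial lipase (2.52 ± 0.22), of the cornified envelope genes SPRR2F (2.24 ± 0.20) and SPRR2A (2.05 ± 0.21), of ZBED2 (2.38 ± 0.25), of TMEM40 (1.79 ± 0.20) and of the collagenase MMP1 (3.63 ± 0.42), with adjusted p from 0.0992 to 0.160. Each of these was higher in both sensitive lines. ZBED2 in H596 and TMEM40 and MMP1 in H2122 were detected after treatment alone, so their means there are set against background. In the resistant lines LIPG, SPRR2F, SPRR2A and ZBED2 were not detected, and TMEM40 (0.23) was detected in HCC366 alone and MMP1 (0.20) in H661 alone. The SPRR2 genes are close copies of each other, and their probes can bind both. Lower in both sensitive lines, also not past the threshold, with adjusted p from 0.160 to 0.239, were the NOTCH ligand JAG2 (-1.65 ± 0.23), the transcription factor genes MYB (-1.25 ± 0.18), E2F2 (-1.50 ± 0.24) and BCL11A (-1.41 ± 0.23), and ANXA9, TMEM184A and PLCB1, whose other probe went up. TMT1A was at least 2.40-fold lower, since it was not detected after treatment.

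Unadjusted p lay under 0.05 for 1418 genes in the sensitive lines, against 695 expected by chance. The call of CYP1A1 uses the spread of all 4 lines: without HCC366 or without H661 its adjusted p was 0.0723, as with the 4 arrays of the sensitive lines alone, without cell line as a block it was 0.303, and without the detection filter 0.366. Without H596 644 genes were called and without H2122 2034, since the lone sensitive line is then assumed to vary like the resistant lines, and without either resistant line 0 were called by limma, with 667 at an unadjusted p under 0.05. Over the 14 alternatives the log2 change of CYP1A1 lay between 5.13 and 7.23 and its adjusted p between 2.40e-08 and 0.366.

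Target genes of the aryl hydrocarbon receptor, a ligand-activated transcription factor that induces enzymes of drug metabolism, rose as a group in the sensitive lines. Of the 10 measured, 9 were higher, with a median log2 change of 1.75 (1.58 with bounded genes at their bound; camera adjusted p = 2.92e-10, and adjusted p = 0.622 with an estimated correlation). Adjusted over the list alone, 7 of the 10 passed. Besides CYP1A1, the log2 change was 2.62 ± 0.34 for CYP1B1 (adjusted p = 0.189) and 2.51 ± 0.42 for TIPARP (adjusted p = 0.239), and CYP1A2 was at least 1.76-fold higher. The list median was 1.54 in H596 and 1.45 in H2122, each above all 10000 random lists of like expression. In the resistant line HCC366 it was 0.51, also at percentile 100 of these lists, with 8 of 10 higher and 4 at least 2-fold higher, and in H661 -0.15, at percentile 1.37. The median level of the list under DMSO in H661 was 4.57, at background, so the value there is no sign of a fall. Random lists were matched on the mean over all 8 arrays and not on levels in H661.

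**Figure D2:**
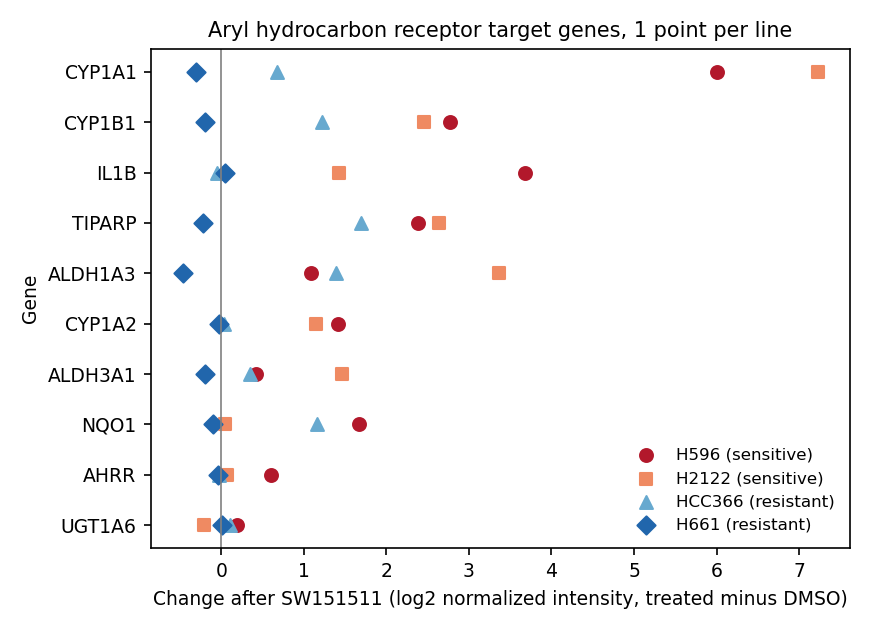
Change after SW151511 (x axis, log2 normalized intensity, treated minus DMSO) of the 10 measured aryl hydrocarbon receptor target genes (y axis), with 1 point per line. CYP1A1 lies at 6.00 in H596, 7.23 in H2122, 0.67 in HCC366 and -0.31 in H661, where it was not detected; in HCC366 it was not detected under DMSO.

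Genes read out by MAPK signalling, which carries growth factor signals to the nucleus, rose as a group, with 20 of 21 higher and a median log2 change of 0.89 (camera adjusted p = 9.36e-11, and adjusted p = 0.622 with an estimated correlation). Adjusted over the list alone, 13 of the 21 passed. The growth factor gene HBEGF changed by 2.01 ± 0.33 (adjusted p = 0.239), and the phosphatase genes DUSP5 and DUSP6, which restrain the same pathway, by 1.56 ± 0.30 and 1.53 ± 0.41, with DUSP6 at 2.46 in H596 and 0.61 in H2122. The list median was 1.56 in H596, where 17 of the 21 were at least 2-fold higher, and 0.35 in H2122, which are also the values without the other line (adjusted p = 3.52e-19 without H2122 and 0.00942 without H596). Heat shock genes rose as a group as well, with 14 of 16 higher, a median of 0.54 (camera adjusted p = 2.67e-06, and adjusted p = 0.622 with an estimated correlation) and 0 past the threshold when adjusted over the list alone. The log2 change was 0.93 ± 0.20 for HSPA1A and 0.81 ± 0.21 for HSPA1B, near-identical chaperone genes whose probes can bind both, and 0.65 ± 0.18 for their partner DNAJB1. The heat shock median was 0.63 in H596 and 0.27 in H2122, and the list passed without either line (adjusted p = 0.0115 without H596).

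Several lists passed through H596 and lost their call without it. NRF2 targets, genes of the response to oxidants, rose as a group (23 of 24 higher, median 0.50, camera adjusted p = 7.01e-07, and adjusted p = 0.622 with an estimated correlation; 1 passing when adjusted over the list alone), and the median was 1.05 in H596 and 0.12 in H2122 (adjusted p = 0.258 without H596). HMOX1, a haem-degrading enzyme gene, had log2 changes of 3.58 in H596 and 2.19 in H2122 (mean 2.88 ± 0.41, adjusted p = 0.218). Interferon response genes fell as a group (21 of 25 lower, median -0.59, -0.61 without 1 gene at background, camera adjusted p = 6.95e-05, and adjusted p = 0.627 with an estimated correlation; 0 passing when adjusted over the list alone). Their median was -1.33 in H596, where 16 of 25 were at least 2-fold lower, and 0.04 in H2122 (adjusted p = 0.123 without H596). The log2 change of IFIT1, an interferon-induced RNA-binding protein gene, was -2.77 in H596, and it was not detected in H2122. Genes of the G2/M phase and mitosis fell as a group (28 of 30 lower, median -0.40, camera adjusted p = 7.01e-07, and adjusted p = 0.622 with an estimated correlation; 0 passing when adjusted over the list alone), with medians of -0.69 in H596 and -0.09 in H2122 (adjusted p = 0.425 without H596). The proliferation marker gene MKI67 changed by -0.64 ± 0.20 and the survivin gene BIRC5 by -0.81 ± 0.21, neither past the threshold. Proteasome genes rose as a group (21 of 23 higher, median 0.33, camera adjusted p = 6.95e-05, and adjusted p = 0.622 with an estimated correlation; 0 passing when adjusted over the list alone), with medians of 0.58 in H596 and 0.05 in H2122 (adjusted p = 0.470 without H596).

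Cholesterol synthesis genes rose as a group (14 of 17 higher, median 0.47, camera adjusted p = 0.000321, and adjusted p = 0.622 with an estimated correlation; 1 passing when adjusted over the list alone) and rested on H2122, where the median was 0.77, against 0.03 in H596 (adjusted p = 0.997 without H2122). The squalene epoxidase gene SQLE changed by 1.08 ± 0.19 and the isopentenyl isomerase gene IDI1 by 1.05 ± 0.30, with IDI1 at 0.48 in H596 and 1.63 in H2122. Fatty acid synthesis genes rose as a group too (9 of 13 higher, median 0.37, 0.39 without 1 gene at background, camera adjusted p = 0.00803, and adjusted p = 0.622 with an estimated correlation; 2 passing when adjusted over the list alone), with medians of 0.48 in H2122 and 0.05 in H596 (adjusted p = 0.345 without H2122). In all, 19 of 45 lists passed in the sensitive lines, 13 higher and 6 lower, and 0 with an estimated correlation. The inflammatory cytokine gene IL1B changed by 2.55 ± 0.48 (adjusted p = 0.264), with 3.68 in H596 and 1.43 in H2122, the cell cycle inhibitor gene CDKN1A by 1.17 ± 0.18 and the stress hormone gene GDF15 by 1.14 ± 0.19 (adjusted p = 0.239 for both).

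**Figure D3:**
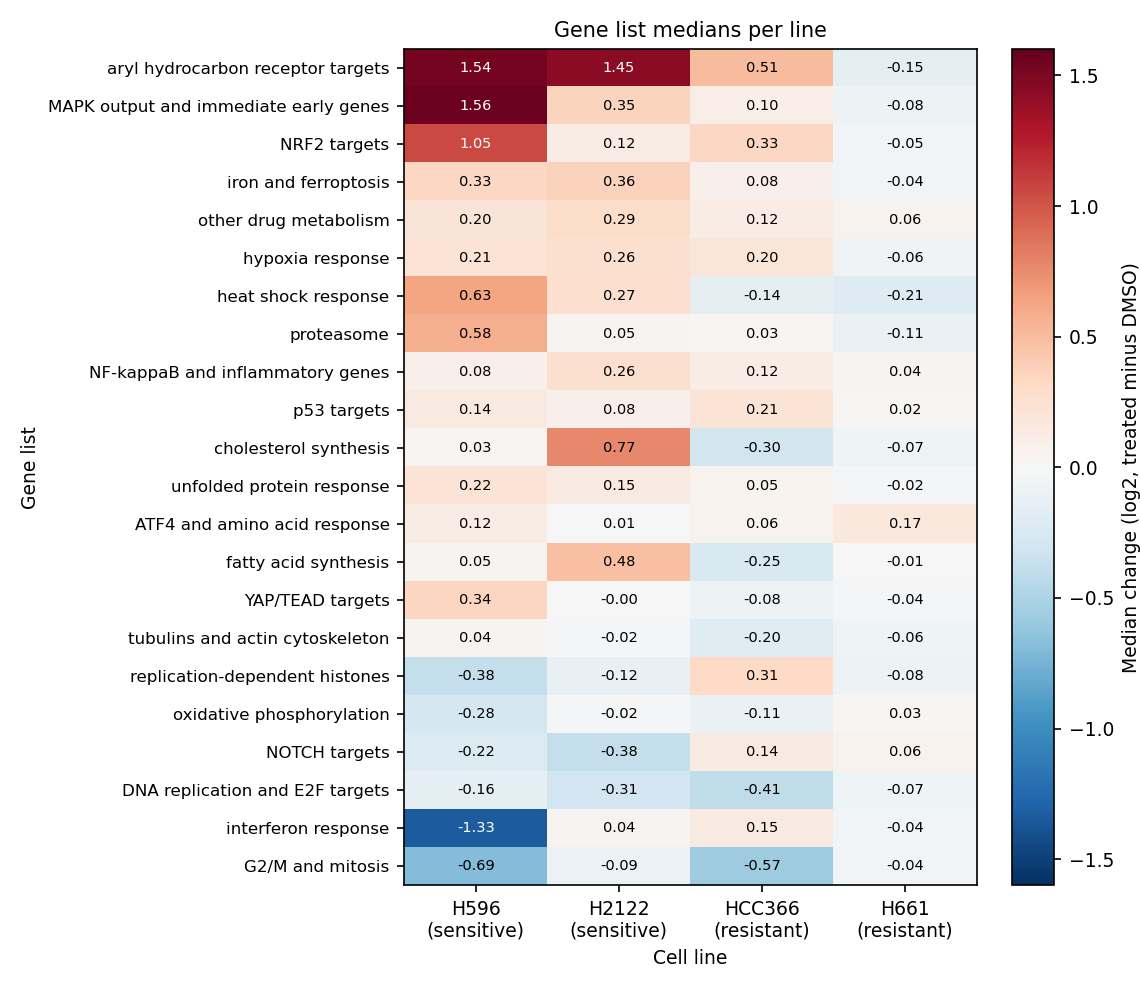
Median log2 change (colour and printed value, treated minus DMSO) of the gene lists (y axis) that passed in the sensitive lines, in the resistant lines or in their difference, per cell line (x axis). The aryl hydrocarbon receptor targets are at 1.54 and 1.45 in the sensitive lines H596 and H2122, and the interferon response at -1.33 in H596 and between -0.04 and 0.15 in the other lines.

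The effect in the resistant lines asks what the compound does in cells said to withstand it. Genes of the G2/M phase and mitosis were lower in 30 of 30, with a median of -0.33, and fell as a group (camera adjusted p = 6.48e-09, and adjusted p = 0.857 with an estimated correlation). DNA replication genes fell as a group as well, with 27 of 28 lower and a median of -0.21 (camera adjusted p = 2.82e-08, and adjusted p = 0.857 with an estimated correlation). Both lists rested on HCC366, where their medians were -0.57 and -0.41, against -0.04 and -0.07 in H661 (adjusted p = 0.859 and 0.711 without HCC366). The log2 change over both lines was -0.63 ± 0.29 for TOP2A, the mitotic DNA topoisomerase gene, -0.53 ± 0.26 for FOXM1, a mitotic transcription factor gene, and -0.55 ± 0.18 for the replication licensing gene CDT1. Genes of the ATF4 amino acid response rose as a group (21 of 29 higher, median 0.10, camera adjusted p = 0.0234, and adjusted p = 0.857 with an estimated correlation), with a median of 0.17 without HCC366 (adjusted p = 0.163) and 0.06 without H661. Heat shock genes were lower in 15 of 16, with a median of -0.14 (-0.13 with bounded genes at their bound; camera adjusted p = 0.0234, and adjusted p = 0.857 with an estimated correlation), and did not pass without HCC366 (median -0.21, adjusted p = 0.0733) or without H661 (adjusted p = 0.321).

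limma called 0 genes in the resistant lines, and unadjusted p lay under 0.05 for 149, against 695 expected by chance. The spread between lines is pooled over both phenotypes in this model, and the count is above chance in the sensitive lines and under it in the resistant lines. Adjusted over the list alone, 0 members passed in each of the 7 lists of 45 that passed, 3 higher and 4 lower, and 0 lists passed with an estimated correlation. NRF2 targets were among the 7, with a median of 0.12, or 0.22 without 4 genes at background. Their median was 0.33 in HCC366 and -0.05 in H661. Without HCC366 0 lists passed the camera test, and without H661 11 did. The genes next in order had an adjusted p of 1. STC2 changed by 1.48 ± 0.48, with log2 changes of 2.53 in HCC366 and 0.43 in H661. Genes with like values in both resistant lines were RPTOR (0.73 ± 0.18), which encodes a subunit of the growth kinase complex mTORC1, CASTOR1 (0.65 ± 0.17), which encodes an arginine sensor of that complex, and the pyruvate carboxylase gene PC (-0.83 ± 0.18). The sulfide oxidase gene SQOR changed by 0.87 ± 0.24, with 1.29 in HCC366 and 0.45 in H661. KDM4C was at least 1.50-fold lower.

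The difference between the phenotypes asks whether the compound acted otherwise in sensitive than in resistant lines. Aryl hydrocarbon receptor targets rose more in the sensitive lines, with a median difference in log2 change of 1.52 and 9 of 10 genes in that direction (camera adjusted p = 2.22e-08, and adjusted p = 0.781 with an estimated correlation). Adjusted over the list alone, 5 of the 10 passed. CYP1A1 differed by 6.43 ± 0.51 (adjusted p = 0.158), CYP1B1 by 2.11 ± 0.48 and IL1B by 2.56 ± 0.68 (adjusted p = 0.920 for both). In the resistant lines CYP1A1 was detected on 1 of the 4 arrays, CYP1B1 in HCC366 alone and IL1B on none, so these differences are set in part against values at background. Without H661 the list median was 0.83 (adjusted p = 2.41e-06). Heat shock genes differed by a median of 0.65, with 15 of 16 in that direction (camera adjusted p = 2.22e-08, and adjusted p = 0.781 with an estimated correlation; 0 passing when adjusted over the list alone), and 0.44 without H596 (adjusted p = 0.000219). HSPA1A differed by 1.07 ± 0.29 and HSPA8, the constitutive chaperone gene, by 0.83 ± 0.29. The MAPK list differed by a median of 0.82, with 19 of 21 in that direction (camera adjusted p = 1.66e-08, and adjusted p = 0.781 with an estimated correlation; 2 passing when adjusted over the list alone), but by 0.27 without H596 (adjusted p = 0.0512) and 1.50 without H2122. HBEGF differed by 2.14 ± 0.47 and DUSP5 by 1.93 ± 0.42. Cholesterol synthesis genes differed by a median of 0.54 (14 of 17 in that direction, camera adjusted p = 3.01e-05, and adjusted p = 0.781 with an estimated correlation, with 1 passing when adjusted over the list alone), and by 0.22 without H2122 and 0.95 without H596. Part of this difference was a fall in HCC366, where their median was -0.30, at percentile 0 of random lists, with 13 of 17 lower. Fatty acid synthesis genes had a median of -0.25 in HCC366, with 12 of 13 lower. Interferon genes differed by -0.62 (21 of 25 in that direction, camera adjusted p = 0.000241, and adjusted p = 0.827 with an estimated correlation; 0 passing when adjusted over the list alone), and by 0.17 without H596 (adjusted p = 0.240) and -1.34 without H2122.

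Of 45 lists, 12 passed in this difference, 9 higher and 3 lower in the sensitive lines, and 0 with an estimated correlation (smallest adjusted p = 0.781). limma called 0 of 13907 genes, and unadjusted p lay under 0.05 for 631, against 695 expected by chance. Without H596 187 genes were called and without H2122 1295, with the lone sensitive line assumed to vary like the resistant lines. With the authors' values or without background correction CYP1A1 was called (adjusted p = 0.0343 and 0.0239), as it was without H596 (adjusted p = 4.54e-07) or without H2122 (adjusted p = 2.77e-06); over its 13 alternatives the adjusted p lay between 4.54e-07 and 1. Next in order were SPRR2F (2.32 ± 0.28), LIPG (2.44 ± 0.31) and SPRR2A (2.29 ± 0.30), each with an adjusted p of 0.781 and not detected in the resistant lines, and MMP1 (3.58 ± 0.59, adjusted p = 0.920), not detected in HCC366. In the other direction lay the small GTPase gene RHOU (-2.49 ± 0.44), the WNT feedback gene AXIN2 (-1.58 ± 0.31), MYB (-1.44 ± 0.25), BCL11A (-1.53 ± 0.32) and MACROD1 (-1.46 ± 0.30), each with an adjusted p of 0.920. AXIN2 in both sensitive lines and MACROD1 in H596 were not detected after treatment, and MYB was not detected in H661. RHOU had log2 changes of -2.12 in H596 and -1.39 in H2122, against 1.27 in HCC366 and 0.21 in H661.

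The effect over all 4 lines asks what the compound does whatever the phenotype. Genes of the G2/M phase and mitosis fell as a group, with 30 of 30 lower and a median log2 change of -0.35, or -0.23 without H596 (camera adjusted p = 1.93e-13, and adjusted p = 0.565 with an estimated correlation). Their fall lay in H596 (-0.69) and HCC366 (-0.57), while H2122 (-0.09, percentile 12.2) and H661 (-0.04, percentile 18.1) were within the range of random lists. DNA replication genes fell as a group with 27 of 28 lower and a median of -0.22 (camera adjusted p = 3.35e-08, and adjusted p = 0.445 with an estimated correlation), and medians of -0.16 in H596, -0.31 in H2122, -0.41 in HCC366 and -0.07 in H661. MKI67 changed by -0.51 ± 0.14, TOP2A by -0.59 ± 0.19 and CDT1 by -0.49 ± 0.12, with lower values in 4 of 4 lines. Adjusted over the list alone, 0 members of either list passed. NRF2 targets rose as a group (23 of 24 higher, median 0.33, camera adjusted p = 1.53e-07, and adjusted p = 0.582 with an estimated correlation), with a median of 0.04 without H596 (adjusted p = 0.0155), -0.05 in H661 and 0 members passing when adjusted over the list alone. In the resistant line HCC366 the NRF2 median was 0.33, at percentile 100 of random lists, with 19 of 24 higher and 4 at least 2-fold higher. HMOX1 changed by 1.76 ± 0.49 and SLC7A11, the cystine importer gene, by 1.33 ± 0.37. Hypoxia response genes rose as a group (16 of 20 higher, median 0.13, 0.15 without 1 gene at background, camera adjusted p = 0.000654, and adjusted p = 0.445 with an estimated correlation), and 2 passed when adjusted over the list alone. The hypoxia median lay between 0.20 and 0.26 in 3 lines but was -0.06 in H661, where 9 of 20 were higher and 11 lower. The oxidase gene ERO1A changed by 0.55 ± 0.12, NDRG1 by 0.85 ± 0.21 and the angiogenic factor gene VEGFA by 0.67 ± 0.19, higher in 4 of 4 lines. Genes of the ATF4 response rose as a group by the camera test (17 of 29 higher, median 0.08, adjusted p = 0.00580, and adjusted p = 0.445 with an estimated correlation), and 1 passed when adjusted over the list alone. The ATF4 median was 0.04 without H2122 and 0.12 without H661, and the list passed without any of the lines (adjusted p up to 0.0236). GDF15 changed by 0.87 ± 0.16 and STC2 by 1.28 ± 0.32, higher in 4 of 4 lines.

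limma called 0 of 13907 genes over all 4 lines, with the smallest adjusted p at 0.829, and unadjusted p lay under 0.05 for 744 genes, against 695 expected by chance. Of 45 lists 17 passed, 13 higher and 4 lower, and 0 with an estimated correlation. Genes next in order with lower values in 4 of 4 lines were LRRC45 (-0.77 ± 0.14), the spindle protein gene SPAG5 (-0.63 ± 0.14), NUDT1 (-0.75 ± 0.17), which encodes an enzyme that clears oxidised nucleotides, the centromere protein gene OIP5 (-0.71 ± 0.16) and the protease gene PRSS23 (-0.94 ± 0.23). The xanthine dehydrogenase gene XDH changed by 1.02 ± 0.26 and was not detected in H661. The adjusted p of each was 0.829.

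Under DMSO the sensitive lines were compared with the resistant lines to ask how the phenotypes differed before treatment. Epithelial markers were higher in the sensitive lines, with 20 of 22 in that direction and a median log2 difference of 3.67 (camera adjusted p = 9.57e-18, and adjusted p = 0.763 with an estimated correlation). Adjusted over the list alone, 12 of the 22 passed, and the median without H661 was 3.57. Fibroblast markers were lower in the sensitive lines (9 of 10, median -1.70, -1.67 with bounded genes at their bound, camera adjusted p = 0.0329, and adjusted p = 0.763 with an estimated correlation; 0 passing when adjusted over the list alone). Their median level was 8.54 in H661 and between 4.46 and 4.53 in the other lines, and the list did not pass without H661 (median -0.03, adjusted p = 0.747) or without H2122 (adjusted p = 0.215). Expression of the vesicle trafficking gene RAB25 was at least 107-fold higher, that of MAL2 at least 94.7-fold, that of the transcription factor gene GRHL2 at least 16.5-fold and that of the protease gene ST14 at least 15.4-fold, since none was detected in the resistant lines under DMSO. NRF2 targets were higher too (20 of 24, median 1.54, camera adjusted p = 3.90e-06, and adjusted p = 0.763 with an estimated correlation; 0 passing when adjusted over the list alone), with a median of 0.43 without H2122 (adjusted p = 0.0285) and 2.71 without H596. The reductase genes AKR1C2 and AKR1B10 were at least 164-fold and at least 87.8-fold higher, though AKR1C probes can bind close relatives. Over the alternatives the log2 difference of AKR1C2 lay between 2.79, with the mean of its probes, and 9.60, and that of AKR1B10 between 4.28, without H2122, and 9.34. The folds at bounds hold for the background correction used: without it the log2 difference of RAB25 was 4.77, against 6.98. Aryl hydrocarbon receptor targets were higher as a group (7 of 10, median 1.13, 1.91 with bounded genes at their bound and without 2 genes at background, camera adjusted p = 0.0122, and adjusted p = 0.763 with an estimated correlation; 3 passing when adjusted over the list alone), but not without H661 (median 0.28, adjusted p = 0.189) and with a median of 2.42 without HCC366. ALDH3A1, an aldehyde dehydrogenase gene of that list, differed by 7.61 ± 0.36 (adjusted p = 0.0658) and was not detected in H661, and UGT1A6 was at least 114-fold higher, with probes that can bind other UGT1A forms. TIPARP, also of that list, was lower in the sensitive lines (-1.51 ± 0.49, adjusted p = 0.531).

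Lung squamous markers were higher as a group in the sensitive lines (11 of 12, median 2.08, 1.94 with bounded genes at their bound, camera adjusted p = 0.000580, and adjusted p = 0.763 with an estimated correlation; 1 passing when adjusted over the list alone). The median was 0.26 without H596 (adjusted p = 0.0394) and 3.39 without H2122, and the desmosomal cadherin gene DSG3 had a log2 level of 9.50 in H596 and 5.67 in H2122. Lung adenocarcinoma and alveolar markers were higher as well (7 of 11, median 1.22, 1.27 with bounded genes at their bound and without 1 gene at background, camera adjusted p = 0.0187, and adjusted p = 0.763 with an estimated correlation; 2 passing when adjusted over the list alone), with medians of 0.34 without H661 and 0.48 without H596. The secreted disulfide isomerase gene AGR2 was at least 137-fold and the adhesion gene CEACAM6 at least 97.4-fold higher. Tubulin and actin cytoskeleton genes were lower in the sensitive lines (19 of 22, median -0.79, -0.70 with bounded genes at their bound, camera adjusted p = 9.33e-05, and adjusted p = 0.763 with an estimated correlation; 3 passing when adjusted over the list alone), with a median of -0.49 without H661. The tropomyosin genes TPM2 and TPM1 differed by -5.78 ± 0.51 and -2.52 ± 0.52. YAP/TEAD targets were lower in 12 of 16 (median -0.49, camera adjusted p = 0.0381, and adjusted p = 0.763 with an estimated correlation; 4 passing when adjusted over the list alone), but not without HCC366 (median 0.08, adjusted p = 0.882) or H2122 (median -0.38, adjusted p = 0.215), and with a median of -1.62 without H661 and -1.11 without H596. CCN1 and ANKRD1 of that list differed by -4.12 ± 0.59 and -4.47 ± 0.68, while the coagulation factor gene F3 differed by 4.39 ± 0.45; ANKRD1 was not detected in H2122, nor F3 in H661. The glucose transporter gene SLC2A3 was at least 161-fold lower in the sensitive lines, and TXNIP, which restrains glucose uptake, differed by 6.18 ± 0.50.

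**Figure D4:**
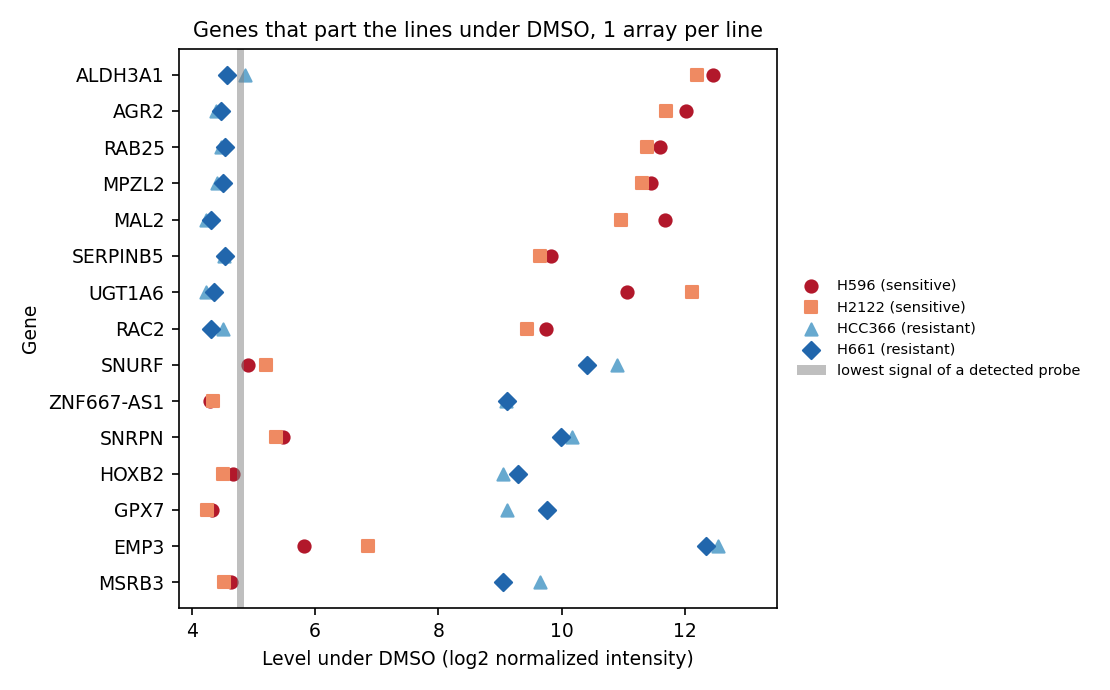
Level under DMSO (x axis, log2 normalized intensity) of genes that part the sensitive from the resistant lines (y axis), with 1 point per line and a grey band at the lowest signal of a detected probe. ALDH3A1 lies at 12.46 in H596 and 12.20 in H2122, against 4.86 in HCC366 and 4.58 in H661.

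limma called 0 of 13907 genes in this comparison of 2 lines with 2, with the smallest adjusted p at 0.0658 and unadjusted p under 0.05 for 1190 genes, against 695 expected by chance. Of 45 lists 13 passed, 9 higher and 4 lower in the sensitive lines, and 0 with an estimated correlation (smallest adjusted p = 0.763). Besides those above, MPZL2 was at least 98.6-fold higher in the sensitive lines, SERPINB5, which encodes maspin, at least 31.6-fold and the GTPase gene RAC2 at least 28.6-fold. The imprinted transcripts SNURF and SNRPN, which share sequence, differed by -5.60 ± 0.39 and -4.65 ± 0.35, and EMP3 by -6.09 ± 0.49. HOXB2 was at least 20.7-fold, GPX7 at least 24.8-fold and ZNF667-AS1 at least 19.7-fold lower, and the adjusted p of these genes lay between 0.0658 and 0.107. Counted over all 8 arrays with line as a random block, 285 genes were called, a fit that counts each line's 2 arrays as 2 values.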

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

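The tests of background correction and of AHR transcript for the aryl hydrocarbon receptor targets, and of the array quality of H661, were chosen only after the result was seen. The gene lists whose change differed between the phenotypes by the camera test were, by their median difference in log2 change (sensitive minus resistant), aryl hydrocarbon receptor targets (1.52), MAPK output (0.82), heat shock response (0.65), cholesterol synthesis (0.54), fatty acid synthesis (0.53), NRF2 targets (0.39), proteasome (0.38), unfolded protein response (0.32), YAP/TEAD targets (0.26), NOTCH targets (-0.20), replication-dependent histones (-0.27) and interferon response (-0.62). With an estimated correlation none of the 12 passed (adjusted p = 0.781 or 0.827). Without H596 the MAPK, NRF2, proteasome, interferon, histone, unfolded protein and YAP/TEAD lists no longer passed (adjusted p from 0.0512 for MAPK to 0.871 for NRF2), and without H2122 neither did cholesterol synthesis (0.478), fatty acid synthesis (0.134) and NOTCH (0.234). Calls were also lost without HCC366 for YAP/TEAD targets (0.0778) and histones (0.0917), and without H661 for NRF2 targets (0.213), NOTCH (0.0580) and the unfolded protein response (0.0575). Among the probes that name no gene, which the comparisons of genes leave out, limma called 1 of 6478 in the sensitive lines, with a log2 change of 2.44 and an adjusted p of 0.0368, and 446 had an unadjusted p under 0.05.

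The rise of aryl hydrocarbon receptor targets in H596 and H2122, with medians of 1.54 and 1.45, and not in H661 (-0.15) is the pattern with the largest difference. In the resistant line HCC366 the median was 0.51, also at percentile 100 of random lists, so the rise is not particular to the sensitive lines. Background correction stretches dim probes, but without it the lower of the medians in the sensitive lines was still 1.29, above all random lists in both, which argues against it as the cause there. In HCC366, where the list lies near background under DMSO (median level 4.82), the median was 0.17 without it (percentile 99.69), so its size depends on the correction. In H661 the level of the list was lower still (4.57), so the median of -0.15 comes largely from genes at background. Less receptor transcript in H661 stays open: under DMSO H661 was 0.15 above the lower sensitive line on the brighter AHR probe and -1.80 from it on the dimmer. On the dimmer probe H661 lay near background, at a log2 level of 4.86, against 10.91 on the brighter. A difference in receptor activity or in exposure to the compound may contribute and was not tested. After treatment AHR itself, chosen after its values were seen, changed by -0.24 ± 0.23 in the sensitive lines (adjusted p = 0.755), with 0.13 in H2122.

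The small response of H661 has 10 genes changed 2-fold, against 69 or more in the other lines. Dimmer or noisier arrays stay open: the lower percent of probes detected on an H661 array, 44.7, exceeds that of every array of the other lines (41.8 to 44.3), but the DMSO array of H661 had the lowest median raw intensity (109.4, against 110.5 or more in the other lines) and its treated array the largest median bead error (3.68%, against 3.63% or less). These differences are small, and more noise would widen changes, while the spread of changes was smallest in H661 (0.22). Of the 617 genes that moved by at least 0.5 log2 on average and the same way in all 3 other lines, 51.1% moved that way in H661, a value consistent with no active compound in that culture. The same value would come from cells that do not respond. In H596, HCC366 and H2122 the percent was 55.3, 62.0 and 64.4, but for genes chosen on only 2 lines, without H661, so these values and that of H661 do not come from the same test. Some lists did shift in H661: ATF4 response genes had a median of 0.17, at percentile 100 of random lists, with 20 of 29 higher, and heat shock genes -0.21, at percentile 0, with 14 of 16 lower. With 1 culture per treatment these shifts do not tell the compound from a difference between cultures. Missing compound and a line that does not respond both stay open. The label resistant does not say whether gene expression responds, and HCC366, which carries it too, had 69 genes changed 2-fold.

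Lower interferon response genes after treatment were seen in H596, with a median of -1.33, and not in H2122 (0.04), HCC366 (0.15) or H661 (-0.04). A lack of room to fall in the other lines is argued against by list members well above background there, whose medians were 0.04 in H2122 (9 genes), 0.17 in HCC366 (17 genes) and -0.16 in H661 (7 genes), against -1.43 in H596 (21 genes). These members were chosen in each line apart, so the medians cover different genes. Under DMSO the median level of the whole list was 9.62 in H596, 5.84 in H2122, 7.71 in HCC366 and 4.92 in H661. Normalization is argued against by the other scalings, under which the value in H596 closest to 0 was -0.99. With 1 array per treatment, a property of the DMSO or the treated culture of H596, such as its density, could not be tested. An effect of the compound in this line is a hypothesis, found and tested on the same data.

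Other splits of the arrays were counted for the effect over all 4 lines. Among the 8 splits that part every pair of arrays of a line, 8 gave as many called genes as the real split (0, highest of the others 0), 2 as many at an unadjusted p under 0.05 (744, highest of the others 751) and 2 as many passing lists (17, highest of the others 17). The 8 splits are too few for a share under 0.05. Among these 8, the other split with 17 lists reversed only the arrays of H661, and so kept the compound effect of the other lines. Of the splits that keep some pairs of a line together, 24 part 2 pairs and gave between 0 and 20 called genes, between 102 and 1873 genes at an unadjusted p under 0.05 (above the real split in 10) and between 2 and 19 lists (above it in 4). With line as a block, such a split holds the compound effect in the 2 parted lines, or the difference between their effects. The highest counts came from parting H596 and H2122 by treatment, which is the effect in the sensitive lines. The counts of these 24 splits are therefore no measure of chance. Of the 3 splits of the lines into pairs, 1 gave as many lists for the difference in effect as the real split (12, highest of the others 10) and 2 as many under DMSO (13, highest of the others 13), and 3 splits are too few for a share under 0.05.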

How the results depend on the processing

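Equal medians, detection on both arrays of a line, and the list counts without background correction and with an offset of 50 were chosen after seeing the data. Genes named in the comparisons kept their direction and their side of the threshold in 4581 results, passed under the alternative alone in 195 (107 without H2122, 54 without H596, 32 with line as a random block, 1 with the authors' values and 1 without background correction), lost their call in 5, all of them CYP1A1 in the sensitive lines, and reversed in 6. As analysed, CYP1A1 in the sensitive lines was the 1 call, so nearly all of the 4581 are genes that stayed uncalled and say little on robustness. Medians of passing lists were kept in 473 results, lost their call in 197 and reversed in 10. Signal over background limits CYP1A1, which was detected on 5 of the 8 arrays and could not be tested when detection on all 8 was required.

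Over all lines and in the resistant lines limma called 0 genes under each of 16 alternatives, with 744 and 149 at an unadjusted p under 0.05 as analysed. In the sensitive lines limma called 0 genes when detection was required on all 8 arrays, where CYP1A1 is no longer tested, with no detection filter, with no line block and with the 4 arrays of the phenotype alone (1893, 83 and 667 genes at an unadjusted p under 0.05 for the last 3), and between 0 and 2034 with a line left out. In the difference 1 gene was called with the authors' values, 1 without background correction, and between 0 and 1295 with a line left out. These high counts came without a sensitive line, when the lone line is assumed to vary like the others. Under DMSO 285 genes were called with line as a random block, which counts each line's arrays as separate values. Lists passing with an estimated correlation were 0 in each of the 5 comparisons (at an unadjusted p under 0.05 there were 3 over all lines, 1 in the difference, 1 under DMSO and 0 in the others), and with fry 1 over all lines (ATF4 response, adjusted p = 0.0202), 0 in the sensitive lines, the resistant lines and the difference, and 1 under DMSO (lung adenocarcinoma and alveolar markers, adjusted p = 0.0217). In the resistant lines between 0 and 11 lists passed with a line left out.

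The percent of genes changed 2-fold in H596, H2122, HCC366 and H661 was 7.23, 2.90, 0.496 and 0.0719. It was 2.73, 0.856, 0.137 and 0.00719 with the authors' values, 4.29, 1.32, 0.266 and 0.00719 with an offset of 50, and 2.55, 0.834, 0.129 and 0.00719 without background correction, and within 1.5 times with detection on all 8 arrays, equal medians and detection on both arrays of a line. A larger offset and no background correction compress the changes of dim probes by construction. For the authors' values the cause was not tested.

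Reversed with a line left out, as the range over the lines, were heat shock (-0.0096 to 0.29) and interferon (-0.41 to 0.10) over all lines, and in the sensitive lines interferon (-1.33 to 0.045), cholesterol (0.025 to 0.77, by the direction of its test), H1-2 (-1.03 to 0.012) and AHR (-0.62 to 0.13). In the resistant lines these were NRF2 (-0.050 to 0.33), hypoxia (-0.059 to 0.20) and STMN1 (-0.74 to 0.029), in the difference NRF2 (-0.030 to 0.92) and interferon (-1.34 to 0.17), and under DMSO other drug metabolism (-0.035 to 1.58), YAP/TEAD targets (-1.62 to 0.078), COL1A2 (-7.90 to 0.21) and THY1 (-4.38 to 0.11), both detected in H661 alone. CTH in the resistant lines was -0.072 with the mean of its probes, since its 2 other probes go the other way. For the rest, leaving out a line leaves the value of the other lines.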

Other observations

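The test of the epidermal gene family was fixed before its result was seen; the line-specific groups and single genes were picked after their values were seen. Genes of MYC and ribosome biogenesis moved in opposite directions in the sensitive lines. Their median log2 change was 0.71 in H596, above all 10000 random lists, with 20 of 21 higher, and -0.64 in H2122, below all random lists, with 19 of 21 lower. The polyamine synthesis gene ODC1 had log2 changes of 1.91 in H596 and -0.79 in H2122, and MYC itself 1.25 and -0.59. In HCC366 the list median was -0.23 and in H661 -0.05. Lung squamous markers had a median of -0.54 in H596 and 0.39 in H2122, with SOX2 at -3.21 and -0.17, KRT15 at -2.60 and at least 0.78, and SPRR1B at 0.17 and at least 2.73, both detected in H2122 after treatment alone. Targets of the nuclear receptors LXR and RAR had a median of -0.57 in H596, with 11 of 12 lower, and 0.42 in H2122, with 9 of 12 higher. The retinol transporter gene STRA6 had log2 changes of -2.22 and 2.13. None of these contrasts between the sensitive lines was tested, since each line has 1 pair of arrays.

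Single genes differed widely between the lines. The cytokine gene IL24 had a log2 change of at least 5.42 in H2122, where it was detected after treatment alone, and of 1.15 in HCC366, and was not detected in H596 or H661. ALDH1A3, which makes retinoic acid, had 3.36 in H2122, 1.39 in HCC366 and 1.08 in H596, and -0.47 in H661. NQO1, a quinone reductase gene of both the NRF2 and the aryl hydrocarbon receptor lists, had 1.66 in H596 and 1.15 in HCC366, against 0.04 in H2122 and -0.10 in H661. Among markers of other cell types, the medians of leukocyte markers (8 genes) lay between 0.01 and 0.12 over the lines, those of fibroblast markers (10 genes) between -0.07 and 0.03, those of endothelial markers (4 genes) between -0.20 and 0.09 and those of erythroid markers (5 genes) between -0.15 and 0.16. Many of these genes lay at background, where a median can hardly move. In the sensitive lines 6 of the 10 fibroblast and 2 of the 8 leukocyte markers were detected on neither side. Without them the medians there were -0.60, against -0.06, and 0.22, against 0.06. With bounded genes at their bound the leukocyte median was 0.08. In the resistant lines all 10 fibroblast markers were detected on both sides, with a median of 0.03.

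Since SPRR2A, SPRR2F and other cornified envelope genes were higher in both sensitive lines, a rise of the whole epidermal differentiation complex was put forward as a hypothesis and tested. Of 61 genes of the family 25 were measured, and with those already named left out 22 remained. Their median was 0.37 in H2122, at percentile 100 of matched random lists, but 0.08 in H596, at percentile 86.0, so a shift of the whole family in both lines was not borne out. In H596 S100A8, S100A9 and S100A4 had log2 changes of -1.53, -1.14 and -1.45. SPRR3 had -0.44 in H596 and at least 1.88 in H2122, where it was detected after treatment alone, and SPRR2D 1.33 and 2.70.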
